A study of Homo sapiens with 9 samples.

How the data were processed

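RNA of SQ20B cells was measured on 9 Affymetrix arrays of a human design with 54675 probe sets, a probe set being a group of short probes for a transcript. The labels give 3 groups of 3 arrays: untreated control, 12 h in 100 nM Gö6976 and 24 h in 100 nM Gö6976. Per the labels' protocols, total RNA was extracted with an RNeasy Mini kit, then amplified and labelled with biotin by a NuGEN Ovation kit. The source names speak of cells, while the growth protocol describes injection of the tumour cells into nude mice, so whether the RNA came from a culture or a tumour is not settled by the labels. The time at which untreated cells were harvested and any vehicle they received are not given in the sources used here. Nothing says that the 3 arrays of a group came from separate cultures or animals, so the p-values measure the spread between these arrays, which may be technical. No pair of arrays held identical values.

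The deposited values are log2 expression per probe set, made with GCRMA per the submitters' processing notes, with no version given there. GCRMA corrects each probe for background with a model of its base composition, brings the arrays to a common distribution and summarises the probes of a set. The scale was found from the values, which ran from 2.21 to 15.65 with a heap of probe sets just above the lowest value. The median over the tested probe sets lay between 8.03 and 8.08 on every array, and 40.1% to 40.7% of probe sets reached 4. Values were used as deposited. For arrays, their number limits the precision, and values near 2.21 carry little signal over background. In 1099 of the tested probe sets, 4.91%, the 3 arrays of a group lay within 0.001 of each other, so the SD of that group is close to 0 and understates its error. FOS, CCN2, DDIT3, PRKD1, MAB21L3 and INHBE are among them.

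In 47 of the 62 array control rows, the row identifiers and the values were in different sort orders. Restoring an order with upper case first put 9 of 9 spiked bacterial and phage controls at 10 or more, against 3 as labelled, and 0 of 27 unspiked bacterial controls there, against 7 as labelled. The restored order is an inference from these values. No other row moved under that sort, and control rows entered no test of gene expression. They served only to compare the 3' and 5' parts of control transcripts.

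Of the 54613 probe sets that are no array control, the 22379 that reached 4 on the log2 scale on at least 3 of the 9 arrays were tested, whatever their group. Genes were named from GEO's platform annotation, and 41091 probe sets had 1 gene symbol, 1801 had several and 11721 were not named here. The symbols were looked up by Entrez ID in the RefSeq gene table of assembly GRCh38.p14, and 0 of them differed. A gene is represented by the tested probe set with the highest mean over all 9 arrays among those naming only that gene, which gave 10353 genes, 4905 of them with more than 1 tested probe set. Genes on the Y chromosome and XIST were left out of the gene tables.

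Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit with a mean per group, contrasts, eBayes). All 9 arrays shared an estimate of the spread, with 6 residual and 2.06 prior degrees of freedom. The comparisons were 12 h against control, 24 h against control and 24 h against 12 h, and a moderated F test covered any difference among the 3 groups. All tests were two-sided, with Benjamini-Hochberg adjustment over the tested probe sets, and a probe set is called changed at an adjusted p under 0.05. Differences are log2 differences with the standard error (SE) of the fit, and group levels are means ± SD over 3 arrays.

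Gene lists of 29 kinds were fixed before the data were examined, with 501 genes of which 347 were measured, and 24 lists had at least 3 measured members and were tested. Each list was tested with camera, which compares its members with all other genes, at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the residuals. The lists were adjusted together within a comparison. The test fry, of whether members move on balance one way or in either direction, was run beside it. Counts of members past the threshold are given over all probe sets and adjusted over the list alone. The genes named were set by a rule fixed at the same time. It took the 10 largest rises and 10 largest falls at 12 h and at 24 h, and the 5 largest each way between 12 and 24 h, among genes past the threshold whose arrays did not overlap between the groups. It added up to 4 members per list with the smallest p in each comparison, and PRKCA, CCNE1, E2F1 and CDKN1A whatever their values. Genes with no approved symbol, Y-linked genes and XIST were left out. List members named outside that rule were chosen after their values were seen.

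The steps were tested on simulated data with 200 changed probe sets among 22379. For 12 h against control, 41.9% of 1.5-fold changes, 82.5% of 2-fold changes and 97.1% of 4-fold changes were recovered. For 24 h against control these shares were 51.8%, 78.9% and 98.3%, and for 24 h against 12 h they were 40.6%, 69.4% and 94.6%. False calls made up 5.2%, 4.5% and 3.5% of the calls in the order given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

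Alternatives were no filter and a stricter filter on dim probe sets, a further quantile normalization, a shift of every array to a common median, an intensity trend with robust spread, array quality weights, fits on only the 6 arrays compared, the replicate number as a block, genes in place of probe sets, omission of probe sets that may cross-hybridise, a 1.5-fold minimum, and omission of each array in turn. Omission of the tied probe sets was added after seeing the data.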

Results

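SQ20B is an established line of human squamous carcinoma cells of the head and neck, and Gö6976 is a kinase inhibitor best known for blocking the calcium-dependent forms of protein kinase C, such as PKC alpha, the product of PRKCA. The title of the series ties PKC alpha to growth and outcome of these tumours, and the comparisons ask which transcripts differ after exposure to the inhibitor. Transcript levels were measured on 9 arrays, 3 of untreated cells, 3 after 12 h and 3 after 24 h in 100 nM Gö6976. Every value below rests on 3 arrays per group. The first principal component over the tested probe sets, with 41% of the variance, put the 24 h arrays at 30.4 to 41.3 and the other 6 at -19.7 to -14.4. The second, with 17.9%, put the third 24 h array at 34.8 and the other 24 h arrays at -24.1 and -16.7. The median SD between arrays of a group was 0.11 in controls, 0.08 at 12 h and 0.15 at 24 h.

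After 12 h in Gö6976, the largest rises were in CCN2, which encodes a secreted matrix protein, and CYP1A1, a cytochrome P450 that metabolises foreign compounds. CCN2 rose by 2.28 ± 0.27 (log2, SE), a 4.86-fold change with an adjusted p of 0.0247, and its relative CCN1 rose by 0.67 ± 0.07. CYP1A1 rose by 2.08 ± 0.21 from a control level of 3.21, below the filter level of 4, so its size depends on the background. FOS, a subunit of the transcription factor AP-1, rose by 1.17 ± 0.09 with an adjusted p of 0.00629, and its 3 control values lay within 0.001 of each other, so this error is understated. The rises of SEC31B, PCSK5, KRT4, FAT3, CYTH2 and WDR90 lay between 0.66 for WDR90 and 1.76 for SEC31B. The long non-coding RNA LINC00937 had the largest fall, -2.18 ± 0.20, followed by the protease inhibitor gene SERPINB3 at -1.36 ± 0.17 and the receptor gene GPR37 at -1.29 ± 0.17. BDKRB2, MAB21L3, SOCS3, TGM1, BCL11B, DSG3 and ACOT11 fell as well, from -1.05 for BDKRB2 to -0.49 for ACOT11. SEC31B in controls (2.88) and GPR37 (2.90) and MAB21L3 (3.99) at 12 h were also below 4, so the sizes and ranks of their differences depend on the background.

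By list, the members that changed at 12 h were few. ATF4, the transcription factor of the amino acid and stress response, rose by 0.65 ± 0.09 as 1 of 18 measured members of the ATF4 and unfolded protein response list (2 higher when adjusted over the list alone). CCN2 and CCN1 were 2 of 12 TGF-beta target genes higher (3 adjusted over the list alone), and FOS was 1 of 24 ERK and AP-1 target genes (3 higher and 2 lower adjusted over the list alone). SOCS3, a feedback inhibitor of cytokine signalling, fell by 0.89 as 1 of 12 STAT3 target genes (3 lower adjusted over the list alone). Of the 17 keratinocyte differentiation genes, KRT4 rose by 0.83 ± 0.10 and TGM1 fell by 0.70 ± 0.10, the same counts as when adjusted over the list alone. The desmosomal cadherin gene DSG3 fell by 0.55 ± 0.08 as 1 of 13 basal keratinocyte and squamous identity genes, also 1 when adjusted over the list alone.

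In the other 23 lists 0 measured members passed limma's threshold at 12 h over all probe sets. Adjusted over the list alone, 4 interferon-stimulated genes were lower and 1 higher, 3 mesenchymal and invasion genes and 2 hypoxia genes were lower, and 1 NF-kB target gene was higher. At an unadjusted p under 0.05, 5 of 31 G2/M and mitosis genes were higher and 0 lower, 4 of 14 glycolysis genes were lower, and 0 of 29 G1/S and E2F target genes and 0 of 10 genes of the PKC and PKD family passed in either direction. PRKCA differed by 0.03 ± 0.11, CCNE1 by 0.11 ± 0.09, E2F1 by -0.08 ± 0.06 and CDKN1A by -0.02 ± 0.08. As sets, camera called 6 lists at 12 h. The G2/M and mitosis list (median 0.14, adjusted p = 7.83e-05) and the ATF4 list (median 0.13, adjusted p = 7.83e-05) were higher than other genes. The glycolysis (median -0.12), basal keratinocyte (median -0.11), hypoxia (median -0.23) and mesenchymal lists (median -0.14) were lower. With an estimated correlation 0 of the 6 calls held, with adjusted p = 0.54 for G2/M, 0.237 for ATF4, 0.356 for glycolysis and for mesenchymal genes, 0.378 for basal genes and 0.468 for hypoxia. By fry, the ATF4 (adjusted p = 0.0384) and mesenchymal lists (0.0397) passed, while G2/M (0.391), hypoxia (0.198), basal (0.119) and glycolysis genes (0.0702) did not. Fry also passed STAT3 (0.0384) and heat shock genes (0.0458) as lower and TGF-beta target genes (0.0384) as higher. Without control replicate 3 the preset calls also ended for G2/M (median 0.06, adjusted p = 0.152) and hypoxia (adjusted p = 0.0522), and without 12 h replicate 1 for the mesenchymal list (adjusted p = 0.0702). The hypoxia median ran from -0.355 to -0.075 over the fits that left out an array. The glycolysis call ended without probe sets that may cross-hybridise (adjusted p = 0.109). The G1/S and E2F target list was lower as a set without control replicate 3 (median -0.05, adjusted p = 0.0463), against a median of -0.01 and an adjusted p of 0.796 on all arrays. Other lists became called without a single array: DNA damage genes (adjusted p = 0.046), interferon-stimulated genes (0.0393) and histone genes (0.0215) without control replicate 1, TGF-beta target genes without control replicate 3 (0.0463), and TGF-beta target genes (0.021) and EGFR family genes (0.0213) without 12 h replicate 3.

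At 12 h, 66 of 22379 probe sets changed, 42 higher and 24 lower, and 25 of them by at least 2-fold. At an unadjusted p under 0.05 there were 2346. The count moved whichever array was left out: it was 18, 8 and 6 without control replicates 1, 2 and 3, 19, 5 and 12 without 12 h replicates 1, 2 and 3, and 22, 27 and 124 without 24 h replicates 1, 2 and 3. Of the 21 named genes past the threshold at 12 h, 20 lost it in 3 to 9 of these 9 fits, with their direction the same, and FOS alone stayed past it in all 9 (adjusted p 0.00387 to 0.048). The count was 14 with no filter on dim probe sets, 28 (13 higher and 15 lower) with only the 6 arrays compared, 49 (21 higher and 28 lower) with genes in place of probe sets, 113 with an intensity trend and robust spread and 284 with array quality weights.

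**Figure D1:**
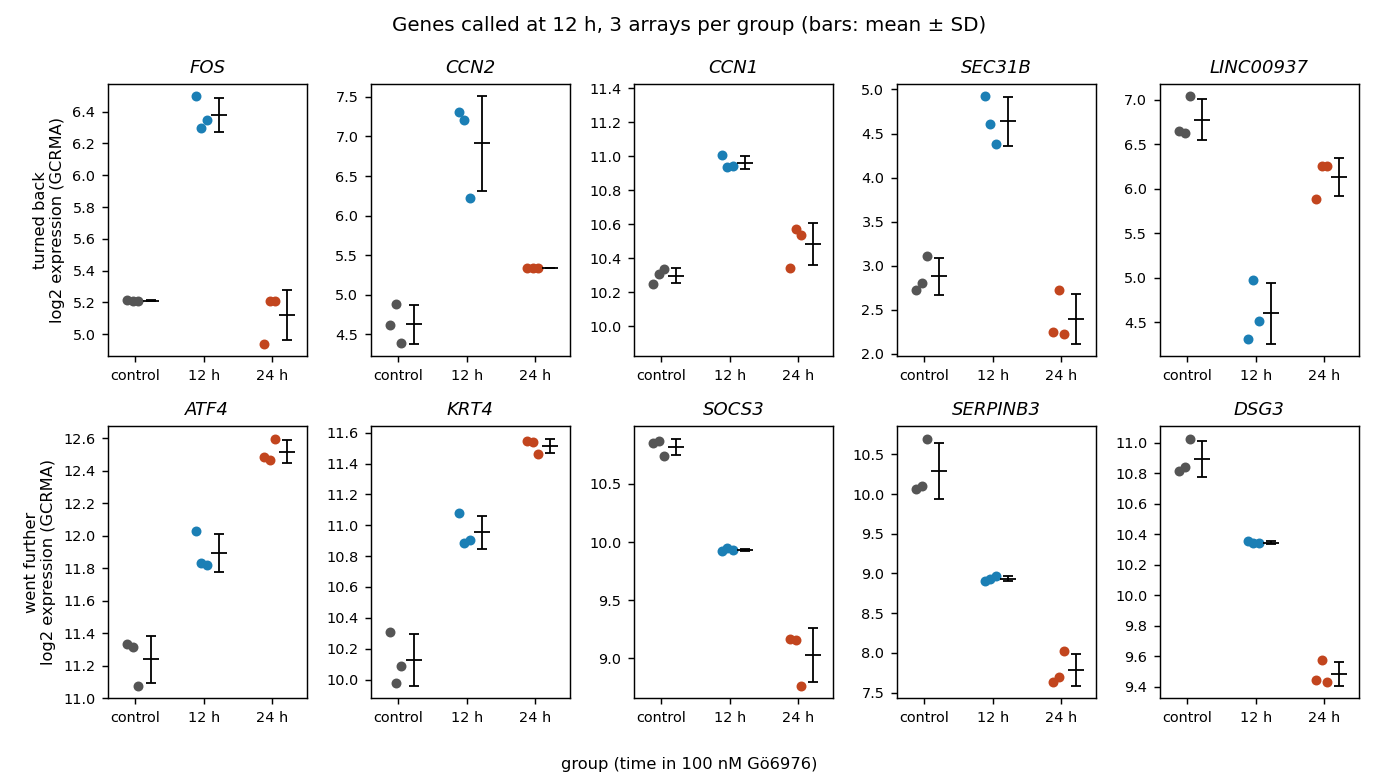
Log2 expression (vertical axes) of 10 genes changed at 12 h, by group (horizontal axes: control, 12 h and 24 h in 100 nM Gö6976); points are arrays, 3 per group, and bars give the mean ± SD. FOS stood at 5.21 in controls, 6.38 at 12 h and 5.12 at 24 h, while SOCS3 went from 10.82 to 9.93 and 9.03.

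Of the 10 largest rises after 24 h in Gö6976, 5 were in genes of the ATF4 and unfolded protein response list: CHAC1, TRIB3, DDIT3, SESN2 and SLC7A11. CHAC1, an enzyme that degrades glutathione, rose by 3.90 ± 0.19, and TRIB3, a pseudokinase induced by stress, rose by 2.90 ± 0.14, or 7.47-fold. DDIT3, which encodes the transcription factor CHOP, rose by 2.58 ± 0.11, SESN2 by 2.35 ± 0.20 and the cystine transporter gene SLC7A11 by 2.26 ± 0.12. STC2 rose by 2.82 ± 0.24, ETV5 by 2.28 ± 0.15, PTX3 by 2.19 ± 0.23, RGS7 by 2.97 ± 0.48 and INHBE by 2.77 ± 0.28. In controls CHAC1 (3.14), RGS7 (3.94) and INHBE (2.23) lay below 4, so the sizes and ranks of their rises depend on the background.

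The largest falls at 24 h were in MAF, a transcription factor gene, by 3.70 ± 0.27 or 13.0-fold, and in WFDC21P, by 3.65 ± 0.19 or 12.5-fold. TGM2, a protein-crosslinking enzyme gene, fell by 3.29 ± 0.32 and MSMB by 3.04 ± 0.29. SERPINB4 changed by -2.81 ± 0.42 and its neighbour SERPINB3 by -2.50 ± 0.17. GBP6 and IFI44L, both genes induced by interferon, fell by 2.75 ± 0.37 and 2.60 ± 0.32, the chemokine gene CXCL14 by 2.63 ± 0.37 and the matrix metalloproteinase gene MMP10 by 2.41 ± 0.17. For each of these genes all 3 treated arrays lay on the same side of all 3 controls, which the naming rule required. Of all tested probe sets, 30.8% were separated in this way, in either direction, at 24 h. SERPINB4, IFI44L and TGM2 ended below 4 at 24 h, so their fall is limited by the floor.

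Of the 18 measured genes of the ATF4 and unfolded protein response list, 11 rose and 2 fell at 24 h (12 and 2 adjusted over the list alone), with a median of 0.93. Besides CHAC1, TRIB3, DDIT3, SESN2 and SLC7A11, the risers included ATF4 by 1.28 ± 0.09, the asparagine synthetase gene ASNS by 1.52, PSAT1 of serine synthesis by 0.93, and ERN1, HERPUD1 and XBP1 by 0.99, 0.94 and 0.56. The members that fell were the endoplasmic reticulum chaperone genes HSP90B1, by 0.32, and PDIA4, by 0.28. HSPA5, the main chaperone of that compartment, differed by 0.07 with an adjusted p of 0.554. The list was called by camera (adjusted p = 2.75e-10), and it was the only list called at 24 h with an estimated correlation (adjusted p = 0.0413).

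Of 31 G2/M and mitosis genes, 24 rose and 0 fell at 24 h (25 and 0 adjusted over the list alone), with a median of 0.68. The B-type cyclin genes CCNB1 and CCNB2 rose by 0.90 ± 0.09 and 0.96 ± 0.11, topoisomerase II alpha (TOP2A) by 0.95 ± 0.10, the securin gene PTTG1 by 0.84 ± 0.08 and the mitotic kinase gene PLK1 by 1.16. The list was called by camera (adjusted p = 1.57e-16) but not with an estimated correlation of 0.484 between members (adjusted p = 0.185). By fry, which does not compare members with other genes, it was higher (adjusted p = 0.00126). Each list that camera called at 24 h passed fry in the same direction, with adjusted p from 4.25e-06 for ATF4 to 0.00555 for interferon-stimulated genes. The NF-kB list passed fry as well (adjusted p = 0.0166). Among 29 G1/S and E2F target genes, the E-type cyclin genes CCNE2 and CCNE1 fell by 0.81 ± 0.16 and by 0.34 ± 0.09, and 0 rose (1 lower adjusted over the list alone; list adjusted p = 0.241, and 0.0108 without control replicate 3). CCNE1 had an adjusted p of 0.0464. It lost its call in 8 of the 9 fits that left out an array, and its adjusted p reached 0.125 without 24 h replicate 2. E2F1 differed by 0.01 ± 0.06. Of 11 CDK inhibitors and D cyclins, limma called 0 changed, with 2 higher at an unadjusted p under 0.05, and CDKN1A, which encodes p21, differed by -0.10 ± 0.08.

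Of 18 DNA damage signalling and repair genes, H2AX rose by 0.71 ± 0.15 and FANCI by 0.40 ± 0.09, and 0 fell (2 and 0 adjusted over the list alone; list adjusted p = 0.211). H2AX lost its call without control replicate 2 or 3 or 24 h replicate 1 or 2 (adjusted p 0.0573 to 0.0629), and FANCI without 24 h replicate 1 (0.0661). Among 17 p53 targets, SESN2 and CCNG1 rose, the latter by 0.27, and TP53I3 and ZMAT3 fell by 0.53 and 0.41 (5 higher and 4 lower adjusted over the list alone; list adjusted p = 0.69). SESN2 is shared with the ATF4 list. Of 18 apoptosis regulators, BIRC5, shared with the mitosis list, rose by 0.50 ± 0.08 and 0 fell, also when adjusted over the list alone (list adjusted p = 0.665).

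Among growth factor and cytokine pathways, 8 of 24 ERK and AP-1 target genes rose and 1 fell at 24 h (10 and 1 adjusted over the list alone; list adjusted p = 0.00332, and adjusted p = 0.226 with an estimated correlation). ETV5, PHLDA1 (1.08 ± 0.11), and the ERK pathway inhibitors SPRED1 (0.64 ± 0.08) and SPRED2 (0.66 ± 0.08) rose, and the phosphatase gene DUSP1 fell by 0.70. Of 9 EGFR family genes and ligands, HBEGF rose by 1.58 ± 0.29, NRG1 by 1.38 ± 0.22 and ERBB3 by 0.40 ± 0.07, and 0 fell (4 and 0 adjusted over the list alone; list adjusted p = 0.0176, and adjusted p = 0.145 with an estimated correlation). That call ended without 24 h replicate 2 (adjusted p = 0.0646) and without probe sets that may cross-hybridise (0.187). Of 12 NF-kB target genes and cytokines, TNFAIP3 rose by 1.12 ± 0.22, CXCL2 by 1.05 ± 0.19, IL1A by 0.94 ± 0.16 and TNFAIP2 by 0.29, and 0 fell (5 higher and 2 lower adjusted over the list alone; list adjusted p = 0.055). The NF-kB list was called without control replicate 2 (adjusted p = 0.0462), control replicate 3 (0.026), 12 h replicate 1 (0.0434) or 24 h replicate 1 (0.0373).

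Of 12 STAT3 target genes, 5 fell and 0 rose at 24 h (5 lower and 2 higher adjusted over the list alone). SOCS3 fell by 1.79 ± 0.11, the interleukin 6 receptor gene IL6R by 0.92 ± 0.08, STAT3 itself by 0.43 ± 0.07 and OSMR by 0.39 ± 0.08. The list had an adjusted p of 0.00806, and adjusted p = 0.145 with an estimated correlation. Of 13 interferon-stimulated genes, 5 fell and 1 rose (8 and 1 adjusted over the list alone; list adjusted p = 0.00622, and adjusted p = 0.188 with an estimated correlation). IFI44L, IRF9 by 0.99 ± 0.15, ISG15 by 0.72 and OASL by 0.58 ± 0.10 were among those that fell (IRF9 to 3.46, below 4, so its fall is limited by the floor), and OAS1 rose by 1.09 ± 0.09. A second, dimmer probe set of OAS1 fell by 0.86 ± 0.16, and the mean of both differed by 0.12 (adjusted p = 0.416).

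Of 13 basal keratinocyte and squamous identity genes, 7 fell and 0 rose at 24 h, also when adjusted over the list alone. The keratin genes KRT14, KRT16 and KRT15 fell by 1.99 ± 0.33, 1.48 ± 0.17 and 0.72 ± 0.07 and DSG3 by 1.41 ± 0.08. The list had an adjusted p of 0.000205, and adjusted p = 0.263 with an estimated correlation. Keratinocyte differentiation genes went both ways, 3 of 17 higher and 5 lower (the same numbers adjusted over the list alone; list adjusted p = 0.665). TGM1, an enzyme of the cornified envelope, fell by 1.98 ± 0.10, SPRR1A by 1.08 and involucrin (IVL) by 0.54, while KRT4, the keratin of inner moist epithelia, rose by 1.39 ± 0.10 and LCN2 by 1.32 ± 0.13. Of 14 mesenchymal and invasion genes, 5 fell and 0 rose (8 lower and 1 higher adjusted over the list alone; list adjusted p = 0.000186, and adjusted p = 0.108 with an estimated correlation). They were MMP10, the collagenase gene MMP1 (-1.64 ± 0.09), the transcription factor gene ZEB2 (-1.59 ± 0.16), the N-cadherin gene CDH2 (-0.62 ± 0.11) and TGFBI (-0.23 ± 0.06), the last of which lost its call in each of the 9 fits that left out an array.

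Of 9 heat shock genes, HSPB1 fell by 0.97 ± 0.12 and HSP90AB1 by 0.36 ± 0.09 at 24 h and 0 rose, also when adjusted over the list alone (list adjusted p = 0.0135, and adjusted p = 0.145 with an estimated correlation). Of 12 cholesterol synthesis genes, FDPS and LSS fell by 0.63 and 0.34 and INSIG1 rose by 0.66, and of 12 TGF-beta target genes ID1 and TGFBI fell, ID1 by 0.57, and ID3 rose by 0.34. Of 12 hypoxia genes VEGFA rose by 0.72 and P4HA1 fell by 0.49, and of 8 histone genes H2BC12 fell by 0.42. These counts were the same adjusted over each list alone, and camera called none of these 4 lists (adjusted p = 0.915, 0.263, 0.915 and 0.987). By limma, on the probe set that stands for each gene, 0 of 14 glycolysis genes and 0 of 14 cytosolic ribosomal protein genes changed, with 2 and 0 lower at an unadjusted p under 0.05. Of 5 other probe sets of the glycolysis gene PGK1, 2 were lower. For the PKC and PKD family 0 of 10 measured genes changed, with 2 lower at an unadjusted p under 0.05, and PRKCA, close to the filter level at 4.74 ± 0.10 in controls and 4.38 ± 0.16 at 24 h, differed by -0.36 ± 0.11 (adjusted p = 0.0737, and 0.0313 without 24 h replicate 3). DLEU2, the host transcript of miR-15a/16-1, and DLEU1, listed with it, differed by 0.38 ± 0.26 and 0.04 ± 0.09.

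Markers of other cell types were few. Of 12 fibroblast markers 4 were measured, of which ACTA2 rose by 0.91 ± 0.17 at 24 h while COL1A1, LUM and DCN did not pass the threshold (-0.78, -0.92 and 0.01, with 1 of 4 other probe sets of DCN higher; 1 higher and 2 lower adjusted over the list alone; list adjusted p = 0.915). Without 24 h replicate 1 the fall of COL1A1 was called (limma adjusted p = 0.0404). Of 10 endothelial markers CDH5 alone was measured and rose by 1.97 ± 0.21, and of 14 leukocyte markers LCP1 alone was measured and fell by 1.75 ± 0.09. Of 8 skeletal muscle markers MB alone was measured (0.39 ± 0.25 at 24 h), and 0 of 7 erythroid markers were. On the same 24 h arrays the actin (ACTB) control probe set for the 5' part of the transcript differed from untreated arrays by -0.61 and the one for the 3' part by -0.04. The 3' minus 5' difference was 2.52 ± 0.15 in controls, 2.57 ± 0.05 at 12 h and 3.09 ± 0.06 at 24 h (exact two-sided permutation p = 0.1 at 24 h, the smallest 3 arrays against 3 allow). In the inferred order of the control rows, the difference moved at 24 h by -0.028 for GAPDH and by -0.116 for the control transcript ISGF3A. Their exact permutation p were 0.6 and 0.4, so these transcripts did not show the shift of ACTB. The ACTB shift stood beside every gene group described at 24 h.

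In all, 2747 of 22379 probe sets changed at 24 h, 1279 higher and 1468 lower, and 453 by at least 2-fold. The count was 1803 without control replicate 2, 1573 with no filter on dim probe sets and 1275 with only the 6 arrays compared. Of the 74 named genes past the threshold at 24 h, 63 stayed past it in every fit that left out an array. The other 11 were CCNE1, FANCI, H2AX and TGFBI, described above, and CCNG1 (lost in 8 of 9 fits), TNFAIP2 (8), HSP90AB1 (7), ID3 (4), ZMAT3 (4), LSS (3) and P4HA1 (3).

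**Figure D2:**
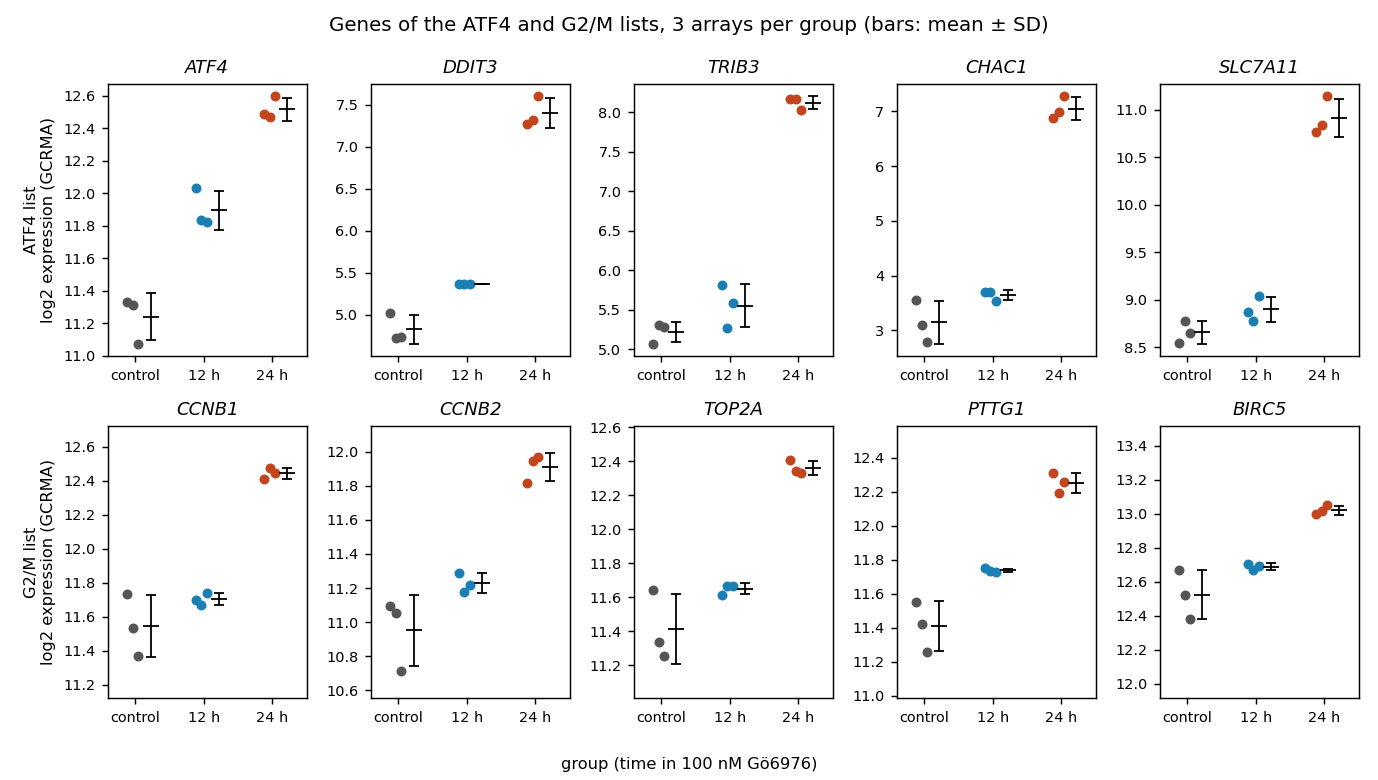
Log2 expression (vertical axes) of 5 genes of the ATF4 list and 5 of the G2/M list, by group (horizontal axes: control, 12 h and 24 h in 100 nM Gö6976); points are arrays, 3 per group, and bars give the mean ± SD. CHAC1 stood at 3.14 in controls, 3.65 at 12 h and 7.05 at 24 h, and CCNB1 at 11.55, 11.70 and 12.44.

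Between 12 and 24 h of exposure, CHAC1 rose by 3.40 ± 0.19, ETV5 by 2.80 ± 0.15, INHBE by 2.77 ± 0.28, PTX3 by 2.58 ± 0.23 and TRIB3 by 2.57 ± 0.14. The largest falls were in WFDC21P (-3.49 ± 0.19), TGM2 (-2.80 ± 0.32), MAF (-2.64 ± 0.27), MSMB (-2.26 ± 0.29) and SEC31B (-2.24 ± 0.19). CHAC1 (3.65), INHBE (2.23) and PTX3 (3.89) at 12 h and SEC31B (2.39) and TGM2 (3.60) at 24 h lay below 4, so the sizes and ranks of these differences depend on the background. This comparison is also the test of whether the effects at both times differ. By any probe set that names 1 gene, 25 genes were higher and 17 lower at 12 h. Of the 24 genes with an approved symbol whose representing probe set changed at 12 h, 10 moved further the same way and 9 moved back. These genes were chosen by their 12 h call and both comparisons use the 12 h arrays, which favours a move back, and no count expected without change was computed. ATF4, KRT4, SOCS3, SERPINB3, DSG3 and TGM1 were among those that moved further, ATF4 by 0.62 ± 0.09 and SOCS3 by -0.91 ± 0.11. FOS (-1.26 ± 0.09), CCN2 (-1.58 ± 0.27), CCN1 (-0.48 ± 0.07) and LINC00937 (1.53 ± 0.20) were among those that moved back.

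By list, 11 of 18 ATF4 and unfolded protein response genes rose between the times and 1 fell (11 and 2 adjusted over the list alone; list adjusted p = 6.35e-08, and adjusted p = 0.0814 with an estimated correlation). Of 31 G2/M and mitosis genes 20 rose and 0 fell, among them CENPF by 0.83 ± 0.10 and TPX2 by 0.71 ± 0.10 (25 and 0 adjusted over the list alone; list adjusted p = 7.11e-13, and adjusted p = 0.397 with an estimated correlation). Of 24 ERK and AP-1 target genes 10 rose and 2, FOS and DUSP1, fell (13 and 3 adjusted over the list alone; list adjusted p = 0.0148, and adjusted p = 0.404 with an estimated correlation). Of 14 mesenchymal and invasion genes 4 fell and 0 rose, MMP10 by 1.68 ± 0.17 and MMP1 by 1.10 ± 0.09 (4 lower and 1 higher adjusted over the list alone; list adjusted p = 0.00352, and adjusted p = 0.237 with an estimated correlation). Of 13 basal keratinocyte genes 3 fell and 0 rose, KRT15 by 0.69 ± 0.07 (6 lower adjusted over the list alone; list adjusted p = 0.0186, and adjusted p = 0.573 with an estimated correlation), a call that ended without 24 h replicate 3 (adjusted p = 0.169).

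The remaining lists were not called by camera between 12 and 24 h. The lists that camera called passed fry as well, with adjusted p from 1.04e-05 for ATF4 to 0.0223 for basal genes. By fry, STAT3 (adjusted p = 0.00211), heat shock (0.00276) and interferon-stimulated genes (0.047) were also lower. The EGFR family (0.0271) and NF-kB lists (0.045) were higher by fry. In the G1/S list CCNE2, CCNE1 and PCNA fell by 0.80 ± 0.16, 0.45 ± 0.09 and 0.30 ± 0.07 and 0 rose (3 lower adjusted over the list alone; list adjusted p = 0.214). Of 12 STAT3 target genes 3 fell, including IL6R by 0.85 ± 0.08, and of 12 hypoxia genes 4 rose, VEGFA by 0.60 ± 0.12 among them, both also when adjusted over the list alone (list adjusted p = 0.0595 and 0.0845). HBEGF rose by 1.91 ± 0.29 and ERBB3 by 0.39 ± 0.07 in the EGFR family list (2 also adjusted over the list alone; list adjusted p = 0.222), and in the NF-kB list TNFAIP3 rose by 1.11 ± 0.22 and IL1A by 0.91 ± 0.16 while PTGS2 fell by 0.80 ± 0.19 (3 higher and 1 lower adjusted over the list alone; list adjusted p = 0.168). Of the 64 named genes past the threshold between the times, 45 stayed past it in every fit that left out an array, and of those named here PCNA lost it in 7 of 9 fits, PTGS2 in 6, VEGFA in 4, CCNE1 in 3 and CCNE2 in 2. PRKCA differed by -0.40 ± 0.11 (adjusted p = 0.0559), E2F1 by 0.09 ± 0.06 and CDKN1A by -0.08 ± 0.08. The medians and means over members had opposite signs for the G1/S and CDK inhibitor lists at 12 h, the apoptosis regulators at 24 h and between the times, and cholesterol synthesis between the times, lists that were not called there. For cholesterol synthesis at 12 h and fibroblast markers between the times, the direction of the test differed from both. The list of STAT3 target genes became called without 12 h replicate 3 (adjusted p = 0.0384) or 24 h replicate 3 (0.0214), and the list of hypoxia genes without control replicate 3 (0.0119). The list of interferon-stimulated genes (adjusted p = 0.0595) became called without control replicate 1 (0.0308) or 3 (0.048), 12 h replicate 3 (0.0331) or 24 h replicate 3 (0.0396).

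Between 12 and 24 h, 2708 probe sets changed, 1333 higher and 1375 lower, and 388 by at least 2-fold. The count was 4959 with array quality weights and 1265 with no filter on dim probe sets. It was 1212, 1143 and 1246 without 12 h replicates 1, 2 and 3. In the F test 2750 probe sets differed among the 3 groups, and the count was 1687, 1601 and 1650 without 12 h replicates 1, 2 and 3, and 1778 and 1698 without 24 h replicates 1 and 2.

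The 12 h and 24 h comparisons share their control arrays. Of the probe sets changed at both times, 13 were higher at both, 19 lower at both and 2 in opposite directions. Independent lists of these sizes would share 2.4 higher and 1.57 lower. Simulated unchanged groups against shared controls gave 0.01 called at both. That simulation held no changed probe sets, so its count was bound to be near 0 and is no baseline for this overlap. The log2 differences had a covariance of 0.033 across probe sets, against 0.015 in the simulation, a difference of 0.018, and a correlation of 0.38, against 0.50 in the simulation. With 3 controls they could not be split, so part of the overlap may come from the shared controls.

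**Figure D3:**
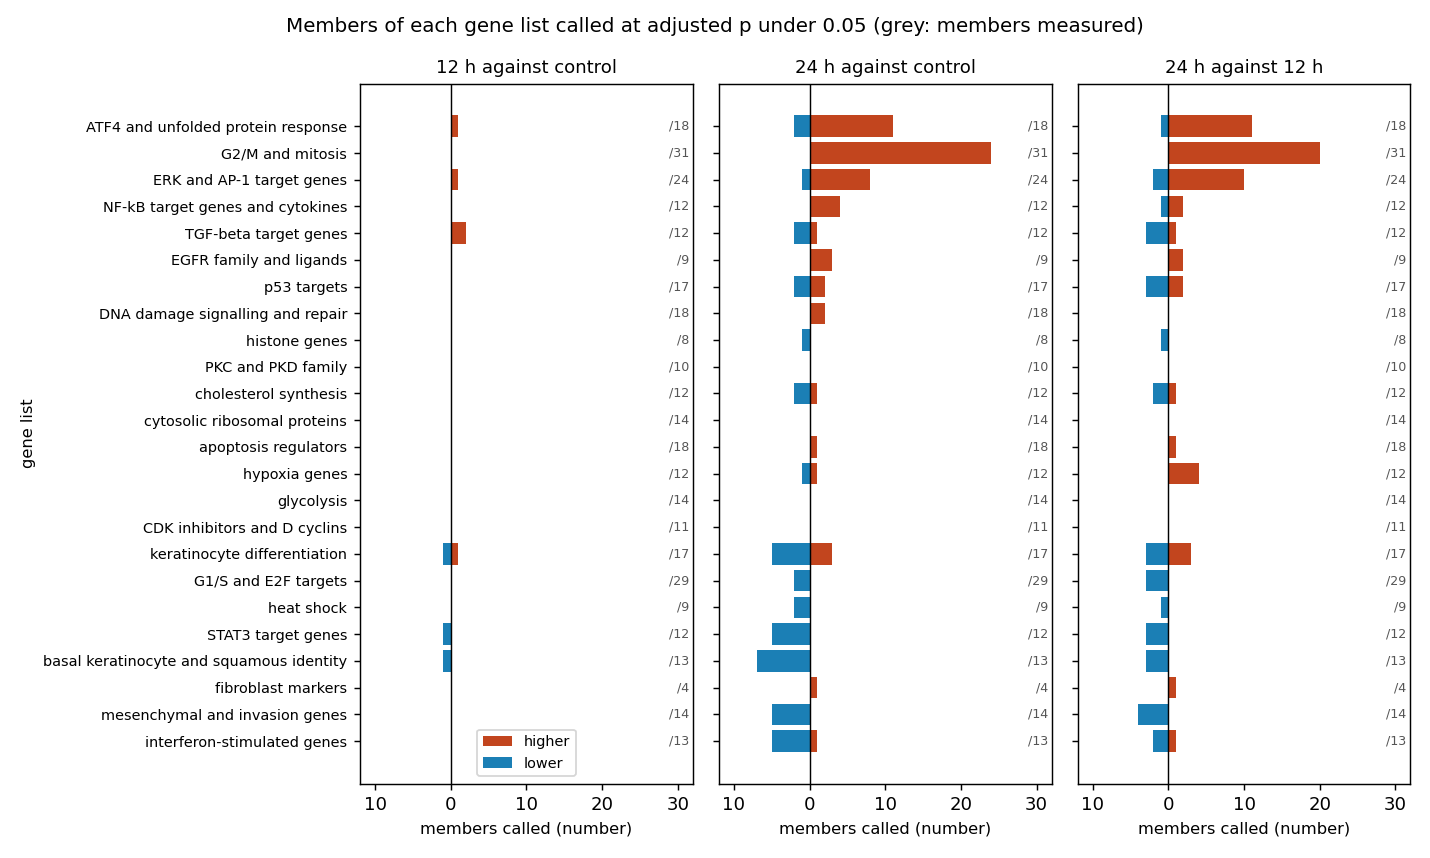
Number of members (horizontal axes) of each of the 24 tested gene lists (vertical axis) that were higher (red, to the right of 0) or lower (blue, to the left of 0) at an adjusted p under 0.05, in the 3 comparisons; grey numbers give the members measured. The G2/M list had 24 of 31 members higher at 24 h and 0 at 12 h.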

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

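The tests on the third 24 h array alone, the GAPDH control, the endoplasmic reticulum chaperones and a wrong label were chosen only after the result was seen. Genes that changed at 12 h and moved back by 24 h stood out because the limma comparison of the times passed the threshold in the opposite direction. Between 12 and 24 h the differences were -0.478 for CCN1, -1.575 for CCN2, -1.257 for FOS, -2.244 for SEC31B, -0.373 for CYTH2, -0.466 for PCSK5, -0.334 for WDR90 and -0.598 for ATXN2L, which had all risen at 12 h, and 1.529 for LINC00937, which had fallen. Their choice by the 12 h call favours a move back, since both comparisons use the 12 h arrays. ATXN2L lies outside the naming rule and was chosen after its values were seen.

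Among data outside the comparisons, 7 unspiked bacterial control rows stood at 10 or more as labelled, where a low signal belongs, and 0 did after their order was restored. The control row for the 5' part of ACTB was lower at 24 h by -0.61 on average.

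The count of changed probe sets stood out by its size at 24 h. Of the 10 splits of the 6 arrays, 1, the real one, gave as many at each comparison: 66 at 12 h (highest other 0), 2747 at 24 h (highest other 1) and 2708 between the times (highest other 0), and 10 splits are too few to exclude chance. For the F test, 100 splits were compared, the real one and others drawn at random, and the real one alone gave as many as 2750. The highest other gave 1615, and it kept the 24 h arrays together and mixed controls with 12 h arrays. A chance division of these 9 arrays was excluded there. Chance differences between cultures were not, since the arrays of a group may be technical repeats.

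Of 31 G2/M and mitosis genes 24 rose at 24 h, with a list median of 0.677 (adjusted p = 0.185 with an estimated correlation). The third 24 h array alone was excluded, since the median was 0.695 without it. A shift of probe sets of like brightness was excluded, since the median lay at percentile 100 of 10000 random lists matched on expression, the highest of which reached 0.171. Loss of RNA 5' ends was not excluded: of 3 control transcripts the 3' minus 5' difference rose by 0.574 for ACTB and, in the inferred order of the control rows, moved by -0.028 for GAPDH and by -0.116 for the other. With that explanation open, no biological reading is offered.

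The ATF4 list rose at 24 h with a median of 0.933, and 0.897 without the third 24 h array, which excluded that array as the sole source. The members for endoplasmic reticulum chaperones and degradation, 3 higher and 2 lower, had a median of 0.076. It was 0.932 for the 3 measured amino acid genes that had not been seen first. For all 9 it was 2.258, most of them chosen after they had been seen to rise. The higher members were HERPUD1, XBP1 and ERN1. The chaperone genes HSPA5 (0.068 ± 0.068), DNAJB9 (0.076 ± 0.065) and SDF2L1 (-0.001 ± 0.082) did not pass the threshold. HSP90B1 (-0.317 ± 0.085) and PDIA4 (-0.279 ± 0.064) fell. For these chaperone genes, set apart after their values were seen, the values argue against a rise. A rise of the whole set was not excluded, since members passed the threshold both ways. By camera the set was higher than other genes (p = 0.0415, and p = 0.0784 with an estimated correlation), and fry gave p = 0.000104. A permutation of members between this set and the 3 amino acid genes gave p = 0.099 for the difference of medians. Elapsed time rather than the compound was not excluded, since 0 untreated arrays had a time in their labels. No biological reading is offered for these reasons.

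The third 24 h array stood apart, with 626 probe sets at least 2-fold from its group mates, against 36 to 239 on the other arrays. For a stronger 24 h response, the slope of its deviation on the 24 h effect was -0.131. Whatever the other 24 h arrays share enters that slope with opposite signs and lowers it. On the first principal component this array lay furthest out, at 41.3, against 31.4 and 30.4. A stronger 24 h response was therefore not excluded. A control or 12 h array under a wrong label was excluded, since its mean correlation with its own group, 0.9878, was 0.0045 above the highest with another array, 0.9833. A sample from outside these groups under a wrong label could not be told by this test. A strong steady shift with brightness was excluded, with a Spearman's rho of 0.09. That value lay just under the bound set beforehand and no spread was computed for it, so a weaker shift was not excluded. No biological explanation was tested, because the labels give none.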

How the results depend on the processing

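The alternative without tied probe sets was chosen only after the result was seen. It gave 60, 2672 and 2652 changed probe sets at 12 h, at 24 h and between the times, and 2724 in the F test, against 66, 2747, 2708 and 2750. The count at 12 h was 14 with no filter on dim probe sets, 113 with an intensity trend and robust spread, 284 with array quality weights and 28 with only the 6 arrays compared. The count at 24 h was 1573 with no filter, 1275 with only the 6 arrays compared, 1701 without probe sets that may cross-hybridise and 1273 at a 1.5-fold minimum. Between the times it was 1265 with no filter, 4959 with array weights, 1688 with genes in place of probe sets, 1552 without probe sets that may cross-hybridise and 1186 at a 1.5-fold minimum. In the F test it was 1316 with no filter, 1755 with genes, 1668 without probe sets that may cross-hybridise and 1295 at a 1.5-fold minimum. Genes in place of probe sets, the omission of cross-hybridising probe sets and the 1.5-fold minimum count fewer items by construction, and for the others the cause was not tested.

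Leaving out 1 array, the count ran from 5 (without 12 h replicate 2) to 124 (without 24 h replicate 3) at 12 h and from 1803 (without control replicate 2) to 3659 (without 24 h replicate 3) at 24 h. Between the times it ran from 1143 to 3490 and in the F test from 1601 to 3458, without 12 h replicate 2 and 24 h replicate 3. Fewer arrays give less power by construction, and the cause of the higher counts was not tested. The replicate numbers did not pair the arrays: the 9 correlations between arrays of the same number ran from -0.143 to 0.096, 0 were above 0.1, and 3 of 9 were highest with their own number. With the number as a block the counts were 6, 1933 and 1787, and 1695 in the F test. The median of the G1/S and E2F targets at 12 h, -0.006 on all arrays, ran from -0.052 without control replicate 3 to 0.044 without control replicate 2. Without control replicate 3 the direction of the list's test reversed from up to down (adjusted p = 0.0463), and the cause was not tested. No named gene that changed reversed its direction without an array. Signal over background limits the dim probe sets, among them CYP1A1, INHBE and CHAC1 in controls.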

Other observations

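Of 17 cytosolic aminoacyl-tRNA synthetase genes, which encode the enzymes that charge tRNA with amino acids, 7 rose and 0 fell at 24 h, with a median of 0.09. AARS1 rose by 1.29 ± 0.08, SARS1 by 0.99 ± 0.09, CARS1 by 0.98 ± 0.08 and GARS1 by 0.90 ± 0.08, and YARS1, TARS1 and EPRS1 by 0.72, 0.63 and 0.41. The list was set up after the ATF4 list had been seen, as the hypothesis that these genes rise with it. By camera the set was higher than other genes (p = 4.69e-05, and p = 0.025 with an estimated correlation), as that hypothesis predicts. These p-values were not adjusted over the lists added. The hypothesis came from the same arrays, so its result is no independent support. The rise lay in part of the members, since HARS1 (-0.133), LARS1 (-0.132) and others did not pass the threshold.

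Among circadian clock genes, TEF and NR1D2 rose by 1.94 ± 0.27 and 1.40 ± 0.12 at 24 h and prompted a test of the others. Of those, 2 passed the threshold, PER2 at 0.73 ± 0.10 and NFIL3 at 0.76 ± 0.14, with a fry p of 5.56e-07 for change in either direction, against the 3 set beforehand. With 1 array left out the number was 2 or 3, so it lay under that bound by no more than its spread, and the test could not tell. For CYP1A1, the hypothesis was a rise of aryl hydrocarbon receptor target genes at 12 h. The other members had a median of -0.034 and were not called by camera. CYP1B1 differed by 0.47 ± 0.10 (limma adjusted p = 0.125), and the test could not tell.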
